A study of Mus musculus with 5 samples.

How the data were processed

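Hearts were taken from female mice after bleeding and perfusion with saline, total RNA was extracted with Trizol, and biotinylated cRNA from 6 µg of total RNA was hybridized to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The deposited values, 1 per probe set and array, are expression levels on a log2 scale, running from about 1.9 to 14.3 with nearly equal quartiles on the 5 arrays. The submitters' processing notes name RMA, GCRMA and Partek without versions or roles, so whether RMA or GCRMA gave these values is not given in the sources used here; both methods summarise the probes of a probe set after normalizing arrays together, and they differ in how much of a dim signal they remove as background, which affects the fold of dim probe sets most. Column medians were 4.68, 4.64 and 4.62 on NZB_W arrays 1, 2 and 3, and 4.64 and 4.62 on NZW arrays 1 and 2. No scanner files were analysed here, so there are no detection calls, and brightness relative to the array stands in for signal over background. All 5 columns match a sample, and 0 other columns were present.

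Groups and replicate numbers come from the sample titles. Of 45101 probe sets, 64 are Affymetrix controls, 34958 carry 1 gene symbol in the platform annotation, 932 carry several and 9211 carry none. Symbols were updated through Entrez identifiers against NCBI RefSeq gene names for GRCm38.p6; 34754 probe sets matched, 204 kept the annotated symbol, and 0 changed name. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed and the assembly served only for names and for which genes are neighbours. Each of 18193 genes was represented by its probe set with the highest mean over the 5 arrays, among probe sets with 1 symbol. Genes were kept when that probe set exceeded the median of its array on at least 2 arrays, which left 11902.

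The deposited log2 values were tested as they stand with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SE values are limma's moderated standard errors, SD values are over the arrays of a group, and folds are 2 to the power of the log2 difference. The prior added 1.69 degrees of freedom to the 3 residual ones, and the median SE over genes was 0.107. Probe sets tested separately had their own fit over 22819 probe sets. The 41 gene lists (pathways, cell type markers, and lists of technical state) were written from textbook knowledge before the data were examined, and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were alternatives. A list's median is the median log2 difference of its measured members, and members were also adjusted over the list alone.

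The rule for named genes was also fixed before the data were examined. It takes up to 15 genes per direction that pass the threshold without overlap between groups, or the 8 with the smallest p in a direction where none pass, said not to pass; up to 4 members of each list with the smallest p; and Xist. It gives 164 genes, and the text prints 74 of them, chosen after their values and those under the alternatives were seen. Genes named outside it are marked where they appear.

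Simulated data for 3 arrays against 2 over 11902 genes had independent noise, with 67, 67 and 66 genes changed by 1, 2 and 3 on the log2 scale. The test called 52.2%, 95.5% and 92.4% of these, with 8 false calls among unchanged genes. The adjusted threshold is stricter when fewer genes change, so these shares do not give the share found where few genes differ. Alternatives covered normalization (quantile, median centring), the filter on dim probe sets, the choice of probe set, the variance model, array weights, thresholds, a block on replicate number, leaving out each array, and testing each probe set. A further setting, without NZB_W array 3 and NZW array 2, was added after the data were seen because control probe sets stood apart there. The linear-scale pseudocount listed among the alternatives does not apply to log2 values. Figures were drawn with matplotlib 3.10.9.

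Correlations between arrays over the tested genes ran from 0.972 to 0.993. NZB_W array 3 correlated at 0.977 and 0.982 with the other NZB_W arrays, which correlated at 0.993 with each other, and the NZW arrays correlated at 0.988. The first principal component held 48.9% of the variance and placed NZB_W array 3 at 30.4, with the others between -15.4 and -4.03. The 5' minus 3' difference of the beta-actin control was -1.31 on NZB_W array 3 and -1.19 on NZW array 2, against -0.88 to -0.89 on the others. The 5' probe set for 18S ribosomal RNA read 12.7 on NZW array 2 and 9.97 to 10.5 elsewhere.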

Results

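Whole-heart RNA was profiled on Affymetrix Mouse Genome 430 2.0 arrays in 5 female mice. Of these, 3 were NZB_W F1 mice, a cross of the NZB and NZW strains that develops a spontaneous lupus-like disease with immune complex nephritis, and they had moderate kidney injury by Austin scoring. The other 2 were healthy NZW mice of matched age, and the NZB_W animals were 12 to 15 weeks old. The series was set up as a pilot search for genes that differ in the heart while lupus nephritis develops, and its design implies a single comparison, NZB_W with nephritis against healthy NZW. Strain and disease differ together between the groups, so each difference below is one between these 2 kinds of mice. Titles call the arrays biological replicates, and the number of arrays limits the precision of every value. Xist, the transcript of the inactive X chromosome, was bright on all 5 arrays, with log2 values from 9.81 to 10.5.

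Mtm1, which encodes the phosphoinositide phosphatase myotubularin that is mutated in X-linked myotubular myopathy, was the 1 gene of 11902 to pass the gene-level test. Its brightest probe set (1434278_at) was 9.33-fold higher in NZB_W hearts, with log2 values of 9.14 ± 0.0429 (SD, n = 3) against 5.92 ± 0.0306 (SD, n = 2), a log2 difference of 3.22 (SE 0.061, limma adjusted p = 0.00133). A dimmer Mtm1 probe set (1454904_at) differed by 3.10 (SE 0.17), and another (1416934_at) by -0.18, with a 95% interval from -0.43 to 0.077. Thus 2 of the 3 Mtm1 probe sets carried the difference and 1 did not. The Mtm1 difference was 3.20 to 3.24 with any single array left out, but its adjusted p stayed under 0.05 only without NZB_W array 3 (0.0265) and otherwise lay between 0.0617 and 0.188.

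A further 4 genes had an adjusted p of 0.0986, short of the threshold of 0.05, and they are named here after their values were seen at the looser threshold of 0.1. Serpinb6b, a serine protease inhibitor, was 2.44-fold higher in NZB_W hearts (log2 difference 1.29, SE 0.077). Sdc4, the heparan sulfate proteoglycan syndecan 4, was 3.42-fold higher on its brightest probe set (1.78, SE 0.12), while its other probe set differed by 0.019 (SE 0.14). Gng12, a G protein gamma subunit, was 2.003-fold higher (1.002, SE 0.063) and differed by 0.17 (SE 0.12) on its other probe set. Cdc14b, a dual-specificity phosphatase, was 1.81-fold lower in NZB_W hearts (-0.86, SE 0.058).

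No gene passed the threshold in the lower direction. The 8 genes with the smallest p among those lower in NZB_W were Cdc14b, Elovl7, Stbd1, Amy1, Zfp52, Rhd, Slc6a16 and Pdk1, with adjusted p from 0.0986 to 0.364. In each of them the 3 NZB_W values lay below both NZW values, which a choice by the smallest p favours. Stbd1, which binds glycogen, had the largest difference of the 8, at 3.23 ± 0.442 (SD, n = 3) against 6.36 ± 0.238 (SD, n = 2), or 8.79-fold lower, although its NZB_W mean is at the dim end of the arrays. Slc6a16, a transporter family member, was 3.70-fold lower and Amy1, an amylase, 2.66-fold lower. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 1.66-fold lower at a bright level (9.80 against 10.5). Elovl7, a fatty acid elongase, was 1.94-fold lower.

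Across all 11902 genes, 660 had an unadjusted p under 0.05, of which 299 were higher and 361 lower in NZB_W, against a nominal 595 by chance, and 2 of the 9 other splits of the 5 arrays gave more (738 and 752). In 2075 genes (17.4%) the 2 groups did not overlap, against a share of 20% by chance. When 22819 probe sets were tested separately, 5 passed, all higher in NZB_W: 2 of Reep3 (4.71, SE 0.18, and 4.43, SE 0.16), 1 of Rps9 (3.91, SE 0.15), 1 of Mtm1 and 1 of Pnpt1 (2.65, SE 0.064). The brightest probe sets of Reep3, Rps9 and Pnpt1, which stood for those genes, differed by 0.096 (SE 0.12), -0.0055 (SE 0.073) and -0.10 (SE 0.11). On the probe sets that passed, the NZW means were 4.04 and 3.91 for Reep3 and 3.70 for Pnpt1. These means lay below the array medians, so the sizes of those differences rest on dim values. Reep3, Rps9 and Pnpt1 lie outside the naming rule and were chosen after their values were seen.

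**Figure D1:**
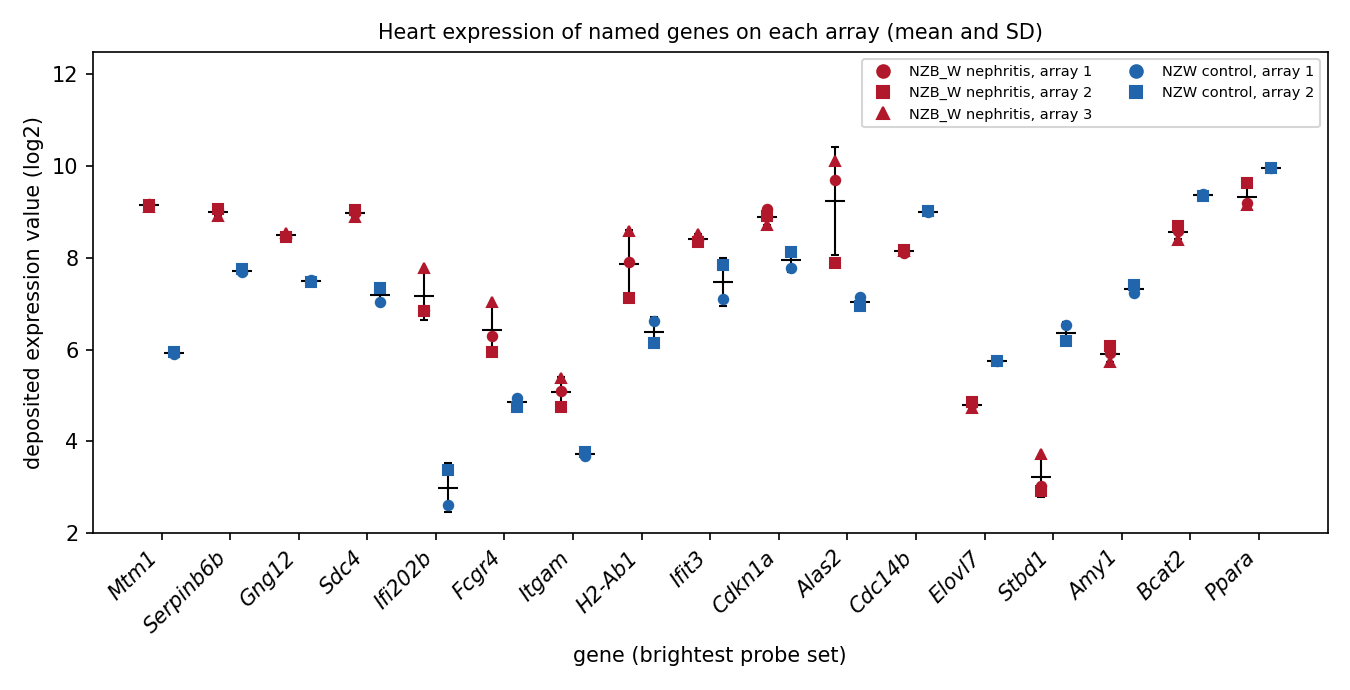
Log2 expression values (vertical axis) of 17 genes on each of the 5 arrays, with NZB_W arrays in red and NZW arrays in blue; black bars give each group's mean and SD. Mtm1 sits between 9.10 and 9.19 on the NZB_W arrays and at 5.90 and 5.94 on the NZW arrays. In all 17 genes, which were picked after their values were seen, the groups do not overlap.

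**Figure D2:**
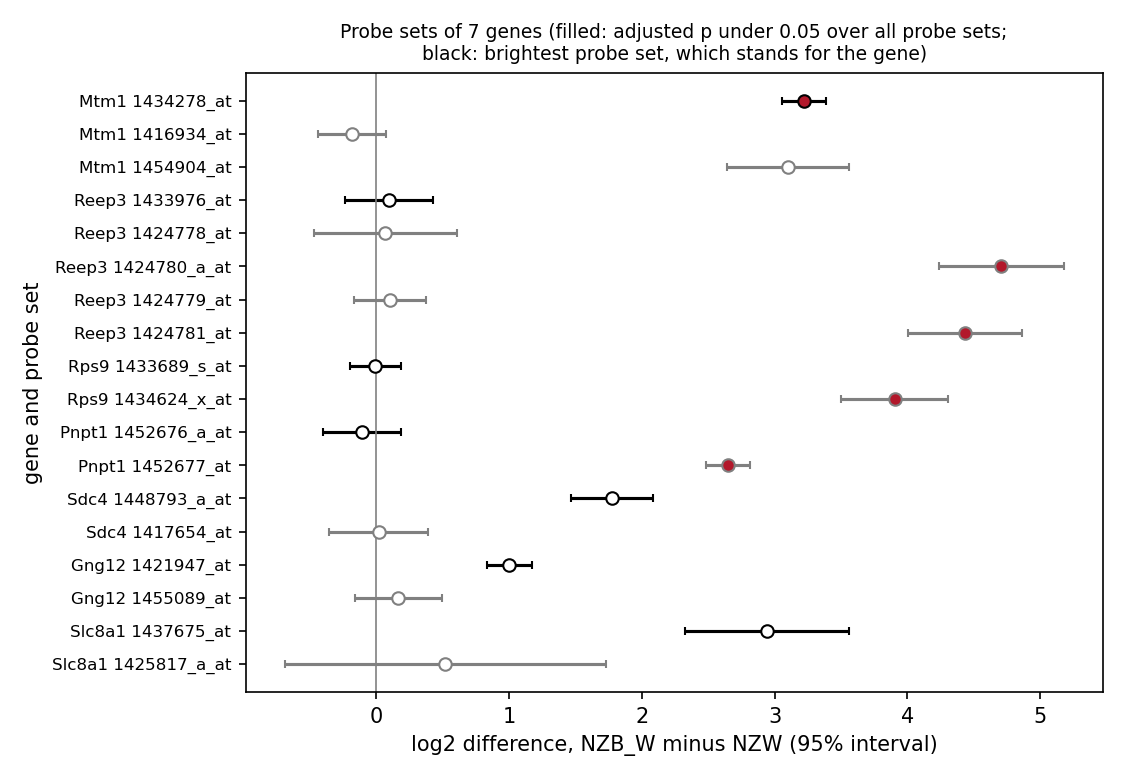
Log2 difference between NZB_W and NZW (horizontal axis, 95% interval) for each bright probe set of 7 genes; filled points passed the test over all probe sets, and black error bars mark the brightest probe set of a gene. Reep3 has 2 probe sets above 4 and 3 near 0, from 0.069 to 0.10.

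Interferon-stimulated genes were higher in NZB_W hearts as a list. Of its 32 measured members, 31 were higher, with a median log2 difference of 0.48, and in 16 of them every NZB_W array exceeded both NZW arrays. Ifit3 was 1.92-fold higher (0.94, SE 0.23), Isg20, an exonuclease, 2.58-fold (1.37, SE 0.41), the transcription factor Irf7 1.85-fold (0.88, SE 0.27) and Usp18, which removes ISG15 from proteins, 1.97-fold (0.98, SE 0.30). The camera test with a preset correlation between genes gave an adjusted p of 6.0e-12 over 41 lists, and an adjusted p = 0.599 with an estimated correlation. No member passed the gene-level test, over all genes or adjusted over the list alone. The median was 0.28 without NZB_W array 3, and Ifit3 differed by 0.58 without NZW array 1.

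The interferon-inducible p200 family and other genes of lupus susceptibility intervals held the gene with the largest log2 difference of all 11902 tested. Ifi202b, a p200 member long studied in NZB mice, was at 7.17 ± 0.528 (SD, n = 3) in NZB_W and 2.99 ± 0.532 (SD, n = 2) in NZW, a log2 difference of 4.18 (SE 0.39, adjusted p = 0.195) or 18.1-fold. Its NZW mean lay below the lower quartile of those arrays (3.27), so the size of this fold rests on a dim value. Fcgr4, an activating receptor for immunoglobulin G, was 2.99-fold higher (1.58, SE 0.34), the p200 gene Ifi204 1.74-fold (0.80, SE 0.18) and Cd48, a SLAM family receptor ligand, 1.73-fold (0.79, SE 0.24). Of its 17 members on the arrays, 9 passed the brightness filter, and 8 of these were higher. When adjusted over the list alone 3 (Ifi202b, Fcgr4 and Ifi204) passed, and 0 passed over all genes. With no filter on dim probe sets the list's median difference was 0.15. The list gave an adjusted p of 3.2e-06 with the preset and an adjusted p = 0.599 with an estimated correlation, and its median difference of 0.57 was 0.29 without NZB_W array 3 and 0.21 without NZB_W array 3 and NZW array 2 together, a setting added after the data were seen.

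Antigen presentation genes were higher in both classes. All 6 measured MHC class II genes were higher in NZB_W, with a median log2 difference of 1.31: H2-Ab1 was 2.81-fold higher (1.49, SE 0.46), H2-Aa 2.60-fold (1.38, SE 0.40), the invariant chain Cd74 2.57-fold (1.36, SE 0.49) and H2-Ea 2.15-fold (1.10, SE 0.42). All 10 MHC class I and antigen processing genes were higher, with a median of 0.63. The immunoproteasome subunit Psmb8 was 1.64-fold higher (0.72, SE 0.24), the peptide transporter subunit Tap2 1.36-fold (0.44, SE 0.16), and H2-D1 and H2-K1 differed by 0.78 (SE 0.30) and 0.81 (SE 0.40). Class II gave an adjusted p of 2.0e-05 and class I one of 2.8e-06 with the preset, both an adjusted p = 0.599 with an estimated correlation, and no member passed the gene-level test, over all genes or adjusted over the list alone. MHC probe sets bind a polymorphic gene family. Of the 7 other bright H2-D1 probe sets, 3 differed by 3.34 to 4.32 and 4 by -0.037 to 0.80. Other bright probe sets of H2-Aa differed by 1.04 and 2.44, of H2-Ab1 by 1.34 and 1.38, and of H2-Ea by 1.59. Without probe sets ending in _s_at, _x_at or _a_at the class II list had under 5 measured members and was not tested. Without NZB_W array 3 and NZW array 2 together the class II median was 0.62 and its call was lost (adjusted p = 0.134). The class I median was 0.34 without NZB_W array 3 and 0.32 without both. Tap2 and H2-K1 differed by 0.29 and 0.445 without NZB_W array 3, and H2-Ea by 0.66 without NZW array 2.

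Macrophage and monocyte markers were higher in NZB_W hearts, in 22 of 23 measured members, with a median log2 difference of 0.64. Itgam, the integrin CD11b, was 2.55-fold higher (1.35, SE 0.20) and was the 1 member that passed when adjusted over the list alone, and 0 passed over all genes. Its NZW mean of 3.73 lay below the array medians, so its fold rests on a dim value. C1qb, a subunit of complement C1q made by macrophages, was 2.02-fold higher (1.01, SE 0.31), Fcgr1 1.899-fold (0.93, SE 0.39) and Cd14 1.56-fold (0.64, SE 0.19). The list gave an adjusted p of 1.3e-09 with the preset and an adjusted p = 0.599 with an estimated correlation. Its array medians, relative to each gene's mean, were -0.0014, -0.056 and 0.81 in NZB_W and -0.11 and -0.54 in NZW, so NZB_W array 3 stood highest, and the median difference was 0.31 without that array, 0.32 without NZW array 2 and 0.126 without both. Fcgr1 differed by 0.58 without NZB_W array 3 and Cd14 by 0.37 without NZW array 2.

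Smaller shifts were found in secreted immune factors. Of 20 chemokines and cytokines, 17 were higher (median 0.19, adjusted p = 0.0026 with the preset and 0.733 with an estimated correlation), with Cxcl9 1.93-fold (0.95, SE 0.30) and Ccl5 1.52-fold (0.60, SE 0.19). Of 15 complement genes, 13 were higher (median 0.11, adjusted p = 0.0064 with the preset and 0.733 with an estimated correlation), with the alternative pathway factor Cfb 1.71-fold higher (0.77, SE 0.18). In neither list did a member pass the gene-level test, and both list calls were lost without NZW array 2 (medians of 0.038 for chemokines and -0.000545 for complement), that of the chemokines also without NZB_W array 3 (0.0068) and with array weights (0.069, adjusted p = 0.216). The complement median was 0.28 without NZB_W array 1, 0.063 without NZB_W array 3 and 0.33 without NZW array 1, and that of the chemokines 0.36 without NZW array 1, where Cxcl9 differed by 0.60. Among B and plasma cell genes, Igha, the immunoglobulin A constant region, was 2.19-fold higher (1.13, SE 0.16) and passed when adjusted over the list alone but not over all genes, and Jchain, which joins immunoglobulin polymers, differed by 1.58 (SE 0.46; 1.001 without NZW array 2), against a dim NZW mean of 4.18. The 12 members as a list did not pass (median 0.017, adjusted p = 0.151), and neither did T and NK cell markers (6 genes, median 0.027, adjusted p = 0.597) or neutrophil markers (5 genes, median -0.16, adjusted p = 0.963).

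Of 8 red blood cell transcripts, 6 were higher in NZB_W hearts (median 0.79, adjusted p = 0.020 with the preset and 0.599 with an estimated correlation), and 0 passed at gene level. Alas2, the erythroid enzyme of heme synthesis, was 4.57-fold higher (2.19, SE 0.71). Slc4a1, the red cell anion exchanger, differed by 2.71 (SE 1.07), against a dim NZW mean of 4.12. Array medians of this list, which overlapped between the groups, were 0.43, -0.40 and 0.92 in NZB_W and -0.39 and -0.56 in NZW, and those of MHC class II were 0.54, -0.19 and 1.19 against -0.48 and -1.10. Hearts had been bled and perfused with saline before collection. Platelet markers did not pass (6 genes, median 0.10, adjusted p = 0.497), and the red cell call was lost with any 1 array left out except NZB_W array 2 (medians of 0.49 to 0.87 in those 4 settings). It was also lost with no filter on dim probe sets (median 0.037, adjusted p = 0.157), without probe sets ending in _s_at, _x_at or _a_at (0.34, 0.482) and with array weights (0.33, 0.216).

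**Figure D3:**
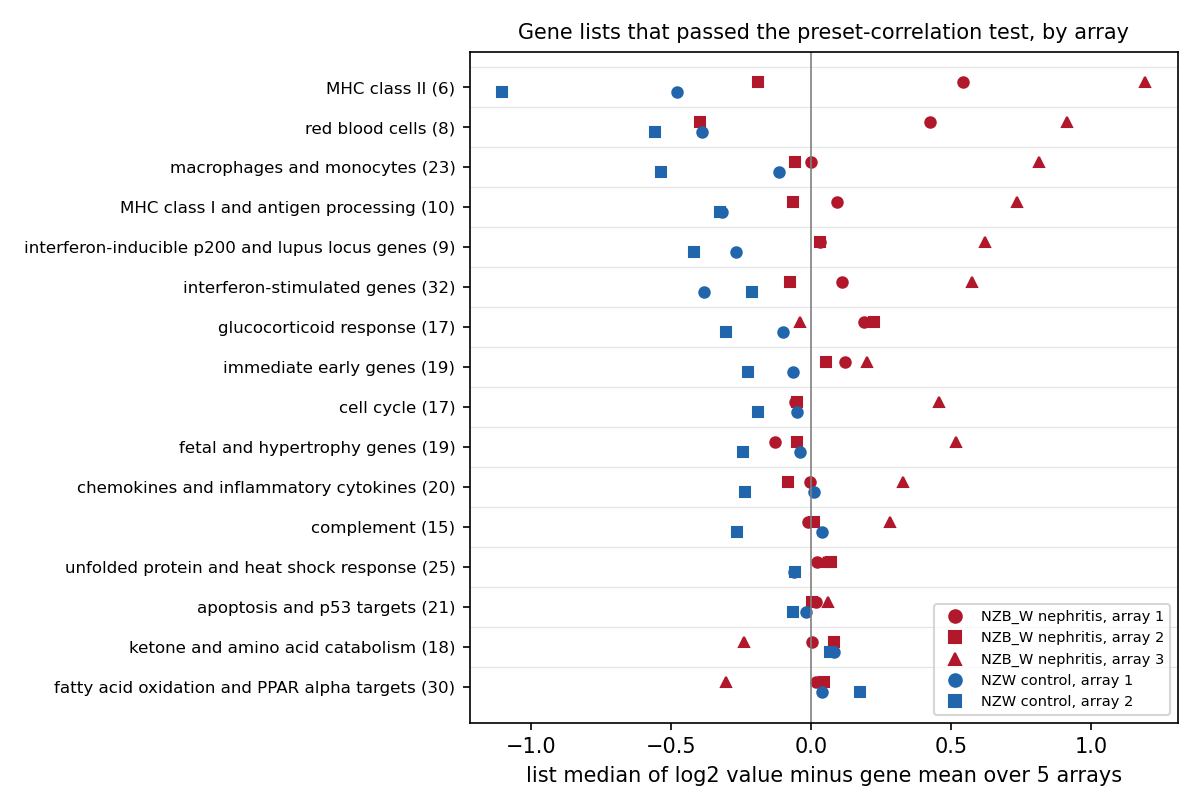
Median over list members of the log2 value minus the gene's mean over the 5 arrays (horizontal axis), for the 16 gene lists that passed with a preset correlation; each symbol is 1 array, NZB_W in red and NZW in blue, and the number of genes follows each name. NZB_W array 3 (triangles) stands highest in MHC class II (1.19) and macrophages (0.81) and lowest in fatty acid oxidation (-0.30).

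Immediate early and glucocorticoid-responsive genes were higher in NZB_W hearts as lists. Both belong to the lists written for technical or other state of the samples, not for a pathway of disease. Of 19 immediate early genes, 17 were higher (median 0.28, adjusted p = 2.0e-05 with the preset and 0.599 with an estimated correlation): the stress transcription factor Atf3 was 1.63-fold higher (0.71, SE 0.14), Zfp36, which destabilizes cytokine mRNAs, 1.67-fold (0.74, SE 0.20), Klf2 1.32-fold (0.41, SE 0.14) and Klf4 1.19-fold (0.25, SE 0.083, with its other bright probe set at 0.042). Of 17 glucocorticoid-responsive genes, 13 were higher (median 0.32, adjusted p = 7.4e-05 with the preset and 0.599 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, was 1.94-fold higher (0.95, SE 0.16) and the transcription factor Cebpd 1.61-fold (0.68, SE 0.12); both passed when adjusted over the list alone and neither over all genes, and the other bright Cebpd probe set differed by 0.19 (SE 0.09). The clock gene Per1 was 1.42-fold higher (0.50, SE 0.12) and the feedback inhibitor of EGF receptor signalling Errfi1 2.05-fold (1.04, SE 0.33). The glucocorticoid list did not lean on NZB_W array 3, whose median of -0.040 lay below those of NZB_W arrays 1 and 2 (0.19 and 0.23), and its median difference was 0.21 without NZW array 2 and 0.20 without both arrays. The immediate early call was lost without NZB_W array 3 and NZW array 2 together (0.11, adjusted p = 0.209).

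Of 25 unfolded protein and heat shock genes, 18 were higher in NZB_W hearts (median 0.070, adjusted p = 0.00080 with the preset and 0.599 with an estimated correlation). Hspa5 differed by 0.30 (SE 0.091), Hsp90b1 by 0.27 (SE 0.087) and the disulfide isomerase Pdia6 by 0.25 (SE 0.067), and no member passed the gene-level test, over all genes or adjusted over the list alone. Another bright probe set of Hspa5 differed by 0.080 and the other one of Hsp90b1 by 0.082, and Hspa5 differed by 0.20 without NZW array 1. The call was lost with the mean of all probe sets of a gene (median 0.057, adjusted p = 0.071). Apoptosis and p53 target genes were higher in 16 of 21 members with a median of 0.048 (adjusted p = 0.043 with the preset and 0.599 with an estimated correlation), and their call was lost with any 1 array left out except NZB_W array 2 (medians of 0.032 to 0.088 in those 4 settings), with no filter on dim probe sets (0.046, adjusted p = 0.070), without probe sets ending in _s_at, _x_at or _a_at (0.061, 0.056) and with array weights (0.041, 0.096). Cdkn1a was the 1 member of that list to pass when adjusted over the list alone.

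Lists of mitochondrial fuel use were lower in NZB_W hearts. Of 30 genes of fatty acid oxidation and PPAR alpha targets, 28 were lower, with a median log2 difference of -0.19 (adjusted p = 1.2e-04 with the preset and 0.745 with an estimated correlation). Ppara, the nuclear receptor itself, was 1.56-fold lower on its brightest probe set (-0.64, SE 0.17), while its 2 other bright probe sets differed by -0.17 (SE 0.16) and -0.13 (SE 0.12). Its targets Acot1 and Angptl4 were 1.54-fold (-0.62, SE 0.21) and 1.94-fold lower (-0.96, SE 0.39), and Acot1 differed by -0.30 without NZW array 2 and -0.94 without NZW array 1. The beta-oxidation dehydrogenase Hadh went the other way at 1.41-fold higher (0.50, SE 0.091). The list's array medians were 0.018, 0.046 and -0.30 in NZB_W against 0.039 and 0.17 in NZW, and without NZB_W array 3 its median was -0.095 and its call was lost (adjusted p = 0.315), as it was without NZW array 2 (-0.11, adjusted p = 0.092). Of 18 ketone and amino acid catabolism genes, 16 were lower (median -0.13, adjusted p = 0.046 with the preset and 0.860 with an estimated correlation). Bcat2, the mitochondrial branched-chain aminotransferase, was 1.75-fold lower (-0.81, SE 0.11) and passed when adjusted over the list alone but not over all genes, and Pccb, a propionyl-CoA carboxylase subunit, was 1.65-fold higher (0.72, SE 0.20). The ketone and amino acid call was lost without NZB_W array 3 (median -0.022), NZW array 1 (-0.14) or NZW array 2 (-0.093), and the median was -0.197 without NZB_W array 2. It was also lost with a stricter filter on brightness (-0.13, adjusted p = 0.074), the mean of probe sets (-0.099, 0.116), array weights (-0.015, 0.826) or no probe sets ending in _s_at, _x_at or _a_at (-0.11, 0.269). Oxidative phosphorylation did not pass, with 32 of 37 genes lower by a median of -0.049 (adjusted p = 0.062), and glycolysis had a median of -0.0083 over 24 genes (adjusted p = 0.963), of which Pdk1 passed when adjusted over the list alone.

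Fetal and hypertrophy genes were higher in NZB_W as a list, in 17 of 19 members with a median of 0.24 (adjusted p = 0.0026 with the preset and 0.733 with an estimated correlation). Myh7, the beta myosin heavy chain of the fetal heart, was 3.25-fold higher (1.70, SE 0.66) with wide spread, at 13.2 ± 0.784 (SD, n = 3) against 11.5 ± 1.08 (SD, n = 2) and a difference of 0.94 without NZW array 1. Skeletal actin Acta1 was 2.06-fold higher (1.05, SE 0.36). Mybpc2 and Ankrd1 differed by 0.81 (SE 0.42; 0.43 without NZB_W array 3) and 0.17 (SE 0.088; 0.11 without NZW array 2). The natriuretic peptides Nppa and Nppb differed by 0.24 (SE 0.38) and 0.38 (SE 0.22), with adjusted p of 0.913 and 0.859, and with 1 array left out Nppa ran from -0.22 (without NZW array 2) to 0.71 (without NZW array 1) and Nppb from 0.13 (without NZW array 1) to 0.63 (without NZW array 2). Array medians of the atrial cardiomyocyte list, which holds Nppa, were -0.72, -0.15 and 0.62 in NZB_W and 0.78 and -0.50 in NZW. Array medians of the list were -0.13, -0.049 and 0.52 in NZB_W against -0.040 and -0.24 in NZW, and without NZB_W array 3 the median difference was 0.024 and the call was lost (adjusted p = 0.101), as it was without NZW array 2 (0.11), while it was 0.39 without NZW array 1. Cell cycle genes followed the same array, with medians of -0.059, -0.050 and 0.46 against -0.050 and -0.19. Of 17, 13 were higher (median 0.25, adjusted p = 0.018 with the preset and 0.789 with an estimated correlation), and the call was lost without NZB_W array 3 (0.014) or NZW array 2 (0.13). It was also lost with a stricter filter on brightness (0.027, adjusted p = 0.508), the mean of probe sets (0.070, 0.111), array weights (0.088, 0.216) or no probe sets ending in _s_at, _x_at or _a_at (0.20, 0.053).

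The contractile and electrical lists did not pass, and of their members Slc8a1 alone passed when adjusted over its list and 0 passed over all genes. Adult sarcomere genes had a median of 0.027 over 19 genes (adjusted p = 0.151), with Csrp3, the muscle LIM protein, differing by 0.34 (SE 0.073), Myoz2 by 0.24 (SE 0.081) and Myh6, the adult alpha myosin heavy chain, by -0.11 (SE 0.061). Calcium handling had a median of -0.029 over 18 genes (adjusted p = 0.963). Within it Slc8a1, the sodium-calcium exchanger, was 7.68-fold higher (2.94, SE 0.23, adjusted p = 0.142 over all genes), while its other bright probe set differed by 0.52 (SE 0.46). Trdn, triadin of the calcium release complex, differed by -0.32 (SE 0.087), with 2 of its 5 other bright probe sets near 0 (-0.023 and -0.021). Cardiac ion channels had a median of -0.072 over 18 genes (adjusted p = 0.241), with the potassium channel subunits Kcna5 and Kcne1 at 0.49 (SE 0.089) and 0.69 (SE 0.17), and the other bright Kcne1 probe set at 0.24 (SE 0.15).

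No list of fibrosis or of resident cells other than macrophages passed, and no member of the lists in this paragraph passed over all genes or over its list alone. Extracellular matrix and fibrosis genes had a median of 0.11 over 36 genes (adjusted p = 0.442), with Lum, lumican, at -0.26 (SE 0.087) and the protease Mmp3 at -1.52 (SE 0.59; -0.64 without NZW array 1 and -2.40 without NZW array 2). Their array medians were -0.46, -0.27 and 0.75 in NZB_W against -0.029 and -0.097 in NZW. Fibroblasts (16 genes, median 0.047), endothelial cells (17, 0.071), smooth muscle and pericytes (14, 0.13), cardiomyocytes (16, -0.039), atrial cardiomyocytes (10, -0.11) and adipocytes (11, -0.33) gave adjusted p of 0.766, 0.079, 0.261, 0.787, 0.597 and 0.169. Skeletal muscle (8, 0.055), valves, nerves and epicardium (9, 0.062) and lung, liver and thymus (6, -0.0035) gave 0.187, 0.597 and 0.821. Endothelial activation (11 genes, median 0.056), acute phase and tissue injury (15, 0.13), renin-angiotensin and natriuretic signalling (12, 0.021), FGF23, Klotho and mineral signalling (13, 0.024) and the circadian clock (17, -0.046) gave 0.261, 0.186, 0.765, 0.766 and 0.765. Oxidative stress defence had a median of -0.0098 over 23 genes (adjusted p = 0.292), with the glutathione transferase Gstm2 1.84-fold higher (0.88, SE 0.18) and the phagocyte oxidase subunit Cybb 2.54-fold (1.34, SE 0.51; 0.86 without NZB_W array 3).

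In all, 16 of the 41 lists passed with the preset correlation, 14 higher and 2 lower in NZB_W, and 0 passed with an estimated correlation (2 with an unadjusted p under 0.05) or with fry (3 with an unadjusted p under 0.05). On simulated data with no difference, the preset called 18 of 40 lists at a correlation of 0.5 between genes, and 0 of 40 with independent noise. Among the 16 lists the estimated correlation ran from -0.031 (unfolded protein) to 0.98 (MHC class II), with apoptosis at -0.022 and immediate early genes at 0.046. Where it is high, a call from the preset alone does not separate a group difference from genes that vary together between hearts. For lists near 0 the simulation at 0.5 does not apply, and their calls too were lost with the estimated correlation. For unfolded protein and apoptosis the estimate lay below the preset of 0.01. Their unadjusted camera p still rose, from 1.7e-04 to 0.025 and from 0.016 to 0.077. A larger correlation between genes therefore did not raise p in these lists. With 3 arrays against 2 there are 10 ways to split the arrays, and an exact permutation test of any single value cannot give a p below 0.1.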

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

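The setting without NZB_W array 3 and NZW array 2 was chosen after the data were seen; the others were planned. The count of changed genes, 1 (1 higher, 0 lower), was the same after quantile normalization, median centring, no filter on dim probe sets, an intensity trend with or without robust fitting, no moderation, and a 2-fold minimum, each of which kept Mtm1. It was 6 (5 higher, 1 lower) with a stricter filter on brightness, which tests fewer genes, 5 (4 higher, 1 lower) with the mean of all probe sets, 2 (2 higher, 0 lower) without probe sets ending in _s_at, _x_at or _a_at, 8 (5 higher, 3 lower) with array weights, 5 (4 higher, 1 lower) at an adjusted p under 0.1, and 5 with every probe set tested. Array weights added Cdc14b, Elovl7, Gng12, Sdc4, Serpinb6b, Slc8a1 and Stbd1, the stricter brightness filter added Cdc14b, Gng12, Sdc4, Serpinb6b and Slc8a1, the mean of probe sets added Cdc14b, Reep3, Rps9 and Serpinb6b, and the stricter probe sets added Pnpt1. Leaving out 1 array gave 0 to 1 changed genes (0 to 1 higher, 0 lower), and the setting without 2 arrays gave 0 (0 higher); these fits have fewer arrays, and a lone NZW array was assumed to vary like the NZB_W arrays. With a replicate block the count was 0 (0 higher, 0 lower), with 1069 genes at an unadjusted p under 0.05 and 1 residual degree of freedom. The titles give the numbers 1 and 2 in both groups without saying whether arrays of the same number were handled together. Deviations correlated at -0.26 for number 1 and 0.10 for number 2. These values cannot tell whether they were, as the deviations of the 2 NZW arrays mirror each other. Number 3 is on NZB_W array 3 alone, so the block takes that array out of the comparison. The block's differences are therefore those found without NZB_W array 3, and it is no separate check. The 16 called lists numbered 11 to 18 under the other planned settings for values, filters, thresholds and the replicate block. They numbered 10 to 19 with 1 NZB_W array left out (10 without NZB_W array 3). Fits without NZW array 2, or without both it and NZB_W array 3, rest on 1 NZW array. With an estimated correlation the count was 0, and with fry it was 0. Unfolded protein and apoptosis had an estimated correlation below the preset of 0.01, so a larger correlation did not raise their p. Why the calls of the other lists were lost, and why fry gave 0, was not tested. Of the 16, the 6 still called without both arrays were interferon, p200, MHC class I, macrophages, glucocorticoid response and unfolded protein. The replicate block ended the calls of chemokines, fetal genes, fatty acid oxidation, ketone catabolism, cell cycle and apoptosis. Outside the settings that left arrays out by name, some calls were kept with medians moved over 1.5 times. With the replicate block they were interferon (0.28), p200 (0.29), MHC class I (0.34), macrophages (0.31), complement (0.063) and red blood cells (0.49). With array weights they were interferon (0.26), p200 (0.38), MHC class I (0.35) and II (0.81), macrophages (0.34), fetal genes (0.090), fatty acid oxidation (-0.11), immediate early genes (0.13) and unfolded protein (0.12). With no filter on dim probe sets they were p200 (0.15) and class II (0.82), and with the stricter brightness filter immediate early genes (0.45). With the mean of probe sets they were fetal genes (0.15), and without probe sets ending in _s_at, _x_at or _a_at complement (0.20). List medians that turned, without a tested cause, were complement (-0.000545 to 0.33 with 1 array left out, and -0.023 without both arrays), chemokines (-0.064), fetal and hypertrophy genes (-0.018) and cell cycle (-0.038), all without both arrays. Of the named genes, Nppa turned (-0.22 to 0.71 with 1 array left out, -0.46 without both) and Xist did with the mean of probe sets (-0.0022); the cause was not tested. These cover the 74 genes printed, which were chosen after values were seen; of the 90 other genes the naming rule gives, 21 changed sign in at least 1 setting. Dim levels limit Ifi202b, Itgam, Jchain, Slc4a1, Neb and the passing probe sets of Reep3 and Pnpt1 in NZW, and Stbd1 in NZB_W. Folds there depend on how background was removed.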

Other observations

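Of the tests in this part, the one on neighbouring genes was written before its result was seen, and leaving out single arrays and testing each probe set were planned; the others were chosen afterwards, among them the setting without both arrays, the splits, the sign test and the comparisons between probe sets of a gene. Over all 11902 tested genes, in a list or not, 33 differed at least 2-fold with an unadjusted p under 0.01, 21 of them higher and 12 lower in NZB_W hearts. They include genes already named above, among them Mtm1, Ifi202b, Slc8a1, Itgam and Stbd1. The genes named next were picked after their values were seen. Il15, a cytokine that sustains NK cells and memory T cells, was 4.07-fold higher in NZB_W (log2 difference 2.02, SE 0.30, adjusted p = 0.488), with all 3 NZB_W arrays above both NZW arrays. Clec4a3, a C-type lectin receptor of myeloid cells, was 3.83-fold higher (1.94, SE 0.44) and Slamf9, a SLAM family receptor, 2.22-fold (1.15, SE 0.26), both with adjusted p = 0.741. Apold1, an endothelial early response gene, was 2.28-fold higher (1.19, SE 0.16, adjusted p = 0.472).

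Metabolic and structural genes were among the rest. Gsta2, a glutathione transferase, was 4.06-fold lower in NZB_W (-2.02, SE 0.37, adjusted p = 0.585). Slc26a7, an anion transporter, was 2.95-fold lower (-1.56, SE 0.22, adjusted p = 0.479), with its other bright probe set at -0.87. Ddah1, which breaks down the nitric oxide synthase inhibitor asymmetric dimethylarginine, was 2.61-fold higher (1.39, SE 0.22, adjusted p = 0.537), and its other bright probe sets stood at 0.73 and 0.77. Neb, the thin filament protein nebulin, differed by 1.49 (SE 0.32, adjusted p = 0.741), against a dim NZW mean of 4.2. Of the 33 genes, 12 had another bright probe set, and in 4 of these (Mtm1, Sdc4, Snhg14 and Cmss1) changes in the amount of whole transcripts are argued against. In each, another bright probe set had a 95% interval wholly below 50% of the near end of the difference's own interval. A further Mtm1 probe set did follow, however. For Snhg14 and Cmss1 the point is weaker. The other Snhg14 probe set had a dim NZW mean of 3.93. That of Cmss1 read 5.48 in NZB_W and 5.85 in NZW, dimmer than the tested one (8.20 and 6.61). In 4 of the other 8 every other bright probe set moved the same way by at least 50% as much. In Slc8a1 the interval of the other one was too wide to tell. In Cytip, Ola1 and Gng12, 1 other bright probe set had its interval below 50% of the difference itself, but not below 50% of the near end. For these 8 genes it stays open.

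The 5 probe sets that passed when each was tested lie in Mtm1, Reep3, Rps9 and Pnpt1, in some but not all bright probe sets of each gene. A change in the amount of the whole transcript is argued against in all 4 genes, because each has another bright probe set whose 95% interval lies wholly below 50% of the near end of the called one's interval. The 5 called probe sets differed by 2.65 to 4.71. Both ends rest on dim NZW means (3.70 for Pnpt1 and 4.04 for Reep3), so these sizes depend on how background was removed. A candidate explanation is a strain variant, homozygous in NZW, that weakens binding of the probes or changes the transcript's end, since an F1 heart keeps 1 NZB allele and would lose only part of its signal. Probe sets that differed at least 4-fold, with an unadjusted p under 0.01, while another of the same gene had its interval wholly below in the same sense came from 5 genes, Reep3, H2-D1, Mtm1, Rps9 and Pnpt1, all lower in NZW, but 5 genes cannot give a two-sided exact sign test p below the 0.0625 found, so it decides nothing; a rule on the values alone, also chosen after the data were seen, adds Slc8a1 and H2-Aa, with all 7 lower in NZW (p = 0.0156). Of all 15 such 4-fold probe sets, 13 were lower in NZW, apart from another or not. Only 11 of the 15 had another bright probe set to be set against, and 0 of these 11 were lower in NZB_W. No gene could thus count against the variant, so neither sign test decides anything. As probe sequences and NZW genotypes were not used here, the strain variant stays a hypothesis, as does a strain difference in transcript form without any link to disease.

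Whether the higher interferon, p200, MHC class I and II and macrophage lists reflect lupus, the NZB genome or the particular hearts cannot be told apart, because strain and disease differ together. NZB_W array 3 alone or NZW array 2 alone as the source stays open: the medians of the 5 lists were above 0 without either (interferon 0.28 and macrophages 0.31 without the first, 0.55 and 0.32 without the second), but with 4 arrays left the 95% interval of the difference between array medians lay above 0 in 1 list (p200) without NZB_W array 3 and in 0 without NZW array 2. Without both, interferon stood at 0.33, macrophages at 0.126, p200 at 0.21 and MHC class I at 0.32, and the class II call was lost. The 10 splits of the 5 arrays are too few for a share under 0.05: 3 of them gave an interferon median as large (0.48 in the real split, 0.55 in the highest other), 5 gave as many called lists (16, highest other 25), 3 as many genes with an unadjusted p under 0.05 (660, highest other 752), and 1 gave as many called genes (1, highest other 0).

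NZB_W array 3 stood apart from the other NZB_W arrays in matrix, cell cycle, macrophage and fuel genes, and its controls had the lowest 5' signal relative to 3', for actin and for GAPDH (-0.156, against 0.048 on NZW array 2 and 0.11 to 0.17 on the others). Lower RNA integrity, shared by this array and NZW array 2, stays open for both. Their deviations from the other arrays of their groups correlated at -0.25 over 11902 genes, where a shared cause alone would give a value above 0. That sets 1 mouse against 1 in NZW and carries any other difference between them, and the control transcripts go with lower integrity. NZW array 2 also stood apart in its poly-A spike controls, with a median of 6.99 against 5.78 to 6.34 on the other arrays. A different sampling of heart tissue stays open too, as atrial markers stood higher there (0.62) than on the other NZB_W arrays (-0.72 and -0.15) and at 0.78 and -0.50 in NZW. Further advanced disease in that mouse stays open and untested, since no label describes single animals.

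A further hypothesis was that local strain haplotypes make neighbouring genes differ together. The rank correlation of absolute t between 11841 neighbouring pairs was 0.0223 in the real split and at most 0.0220 in the 9 others (median 0.014), so the excess was under its standard error of 0.0092 and the test does not decide. A last hypothesis concerned genes lower in NZB_W by more than an NZB allele without signal could give, since an F1 heart keeps 1 NZW allele and additive expression from it would leave the difference at -1 or above. The 95% intervals of 4 genes, which include Stbd1 (-3.89 to -2.38), Slc6a16 (-2.47 to -1.30) and Amy1 (-1.75 to -1.07), lay below -1; 3 of the 10 splits gave as many, with 16 in the highest other. In the other direction the intervals of 9 genes lay above 1; 1 of the 10 splits, the real one, gave as many, with 3 in the highest other, and 10 splits are too few for a share under 0.05 either way.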
